A study of Rattus norvegicus with 40 samples.

How the data were processed

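Total RNA from 4 rat brain regions (hippocampus, amygdala, anterior cortex and cerebellum) was sequenced 12 months after exposure of the rats to a blast or to a sham procedure. Each region had 5 blast and 5 sham libraries, 40 in all. Per the labels, RNA was extracted with Qiazol reagent, purified with RNeasy mini columns and made into libraries with the NEBNext Ultra RNA kit. Groups were taken from the tissue and treatment labels. The titles carry a number, and 10 numbers recur over the regions, 5 of blast and 5 of sham libraries. The labels do not say that a number stands for an animal, so p-values here measure only the spread between these samples. In the table of the amygdala, a sham column bears the number 13 and the matching title the number 12. That library was assigned to the amygdala sham group only and is called the unnumbered library.

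The submitters' processing notes name CASAVA for the reads, without a version. The aligner, the counting tool, the annotation and the genome build are not given in the sources used here. Each region had its own table of Ensembl rat genes, with 23485 genes for the hippocampus, 23783 for the amygdala, 23366 for the anterior cortex and 22831 for the cerebellum. Per the file headers, the authors deposited raw read counts per gene and library, which were whole numbers. The authors also deposited a normalized signal per gene and library, which equalled the count divided by 1 factor per library where this was checked, in all libraries but the unnumbered one. The deposited log2 fold changes of the authors compare blast with sham and are shrunken towards 0. The authors deposited a p-value and an adjusted p-value per gene from a test whose name is not given in the sources used here. FPKM columns were not used. Everything reported as computed here came from the raw counts, and values of the authors' own test are named as such.

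Library totals ran from 11268097 to 37128383 counts. These totals bound counting error, and the spread between libraries was taken from the replicates. The tables hold 25958 gene identifiers, 20814 of them in all 4 tables. The cerebellum table names 4342 identifiers otherwise than the rest, and 25 gene names of the amygdala table had been turned into dates. Genes were therefore joined by identifier and named as in the hippocampus and anterior cortex tables where these held the gene. No column of raw counts was left without a group. A comparison of the 80 pairs of libraries that share a region and a treatment found no duplicates, since the smallest chi-square per degree of freedom was 6.64. Blast libraries were not compared with sham libraries in this way.

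For each region blast was compared with sham by edgeR 4.0.16 with filterByExpr, TMM normalization and two-sided quasi-likelihood F tests. Adjusted p-values are Benjamini-Hochberg (BH) values over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are log2 of blast over sham with their standard error (SE), and group levels are CPM (counts scaled to the library size after TMM) with their standard deviation (SD). The chance expectation beside a count of genes with an unadjusted p under 0.05 is that share of the genes tested. A difference of the blast effect between regions was tested by the F test of the region by treatment interaction in 1 edgeR model of 8 group means. The mean blast effect over the 4 regions was tested by limma 3.58.1 with voom and the title number as a random block of 11 levels, the unnumbered library being a level of its own. Both joint models used genes present in all 4 tables.

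Before the data were examined, 53 gene lists with 970 names in all were fixed. They cover cell types of the brain, neighbouring tissue that a dissection can carry, markers of regions, and themes of injury and stress. Of the names, 41 were not in the tables, 7 were matched by a synonym and 9 were second names of a gene already in the list. Lists with 5 or more measured members were tested in each region by camera of limma on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. List p-values were adjusted by BH over the lists of a region. Each list was also tested by camera with an estimated correlation and by fry, which tests whether the genes of a list move, on balance, one way and does not compare them with other genes. The score of a list in a library is the mean log2 CPM of its members, centred within the region. Camera on the lists for the mean effect over regions was added after the data had been seen. List scores averaged per title number were compared by exact two-sided permutation tests over 252 arrangements of the 10 numbers, with the unnumbered library in the place of number 13.

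Genes to be named were fixed by a rule at the same stage. It took in each region the 10 genes with the smallest p among those higher in blast and the 10 among those lower, and up to 4 members with the smallest p of each list that camera called. For the interaction and for the mean effect it took the 10 genes with the smallest p. Names that stand for a clone or an unnamed locus were passed over. Genes named beyond this rule are said to be chosen after their values were seen.

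Alternatives fixed at that stage as well were DESeq2 size factors, no filter or a filter at 1 CPM in 5 libraries, the DESeq2 1.42.0 Wald test, voom with and without quality weights, 1 model of all 40 libraries, a choroid plexus score as covariate, a threshold of 0.1, other tests of lists, other uses of the title number and the removal of each library in turn. Added after the data had been seen were a surrogate variable from sva 3.50.0, the choroid plexus and fibroblast scores as covariates, the removal of each library's trend with gene length, and the removal of libraries that stood apart. Correlations of log2 fold changes between regions were computed across genes. The comparisons were repeated on 100 drawn splits of the title numbers or libraries into 5 and 5, the real one included. Splits and removals of the mean effect used the block correlation of the real fit.

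The code was tested on simulated counts drawn from the means, dispersions and library sizes of these data. In these, 200 genes above a minimum mean count were given a log2 change of 0.5, 1 or 2. Counts were drawn independently, with no effect shared by the libraries of a number and no libraries that stand apart. The recovery thus does not apply to genes of lower counts, and the false calls may understate those in the real data. The edgeR test recovered 16.4%, 61.2% and 98.5% of them in the hippocampus, 59.7%, 88.1% and 100% in the amygdala, 1.49%, 58.2% and 90.9% in the anterior cortex, and 52.2%, 82.1% and 98.5% in the cerebellum. It made 2, 10, 6 and 6 false calls in these regions, and DESeq2 made 35, 22, 35 and 24. The fit of the mean effect recovered 77.6%, 94% and 100%, with 8 false calls. The test of the difference between regions recovered 14.9%, 64.2% and 89.4% of changes placed in the cerebellum alone, with 4 false calls. Computations ran in R 4.3.3 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.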

Results

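RNA sequencing compared 5 blast and 5 sham libraries in each of 4 rat brain regions, 12 months after exposure. Library totals ran from 11589358 to 19156693 counts in the hippocampus, from 12653267 to 16433786 in the amygdala, from 11268097 to 37128383 in the anterior cortex and from 11655408 to 15551825 in the cerebellum. In sham libraries the marker genes of each region were highest in that region. Hippocampus markers had a mean log2 CPM of 6.01 ± 0.25 (SD, n = 5) in the hippocampus against 4.20 ± 0.11 in the amygdala. Cerebellum markers reached 8.12 ± 0.06 in the cerebellum, and amygdala markers 3.81 ± 0.09 in the amygdala. Cortical layer markers were highest in the anterior cortex at 5.48 ± 0.15, where striatum markers stood at 4.76 ± 0.21, also their highest level over the regions. Gene positions below are as the tables give them, and the genome build is not given in the sources used here.

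In the hippocampus of rats 12 months after blast, genes of motile cilia, of ependymal cells, of myelin and of reactive astrocytes rose against the other genes by camera (n = 5 blast and 5 sham libraries). Camera called as many lists or more in 46 of 100 splits into 5 and 5, the real one included, so chance stays open. All 14 cilium genes measured were higher in blast, with a median log2 fold change of 0.64 (adjusted p = 2.98e-06, and 0.408 with an estimated correlation). Among them the cilia and flagella associated genes Cfap43, Cfap44 and Cfap65 had log2 fold changes of 0.66 ± 0.29 (SE), 1.03 ± 0.55 and 0.90 ± 0.47. All 18 oligodendrocyte and myelin genes were higher, by a median of 0.22 (adjusted p = 0.00284, and 0.849 with an estimated correlation), among them Mobp, which codes for a myelin protein, at 0.32 ± 0.19. The myelin score was low in sham libraries Hip_11 (-0.48) and Hip_33 (-0.82). In sham libraries Hip_13, Hip_14 and Hip_15 it was 0.24, 0.23 and 0.28, against -0.15 to 0.39 in blast. Of 13 reactive astrocyte genes 11 were higher, by a median of 0.24 (adjusted p = 0.0016, and 0.408 with an estimated correlation). The sphingosine receptor gene S1pr3 stood at 0.37 ± 0.14 and Gfap, the filament protein of astrocytes, at 0.23 ± 0.12, with 1282 ± 156.5 CPM (SD) in blast.

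Genes of the immune and matrix groups were also higher in blast hippocampus. Of 19 antigen presentation genes 17 were higher, by a median of 0.23 (adjusted p = 0.00869, and 0.849 with an estimated correlation), among them Cd74, the invariant chain of class II complexes, at 0.63 ± 0.29. Of 16 complement genes 11 were higher, by a median of 0.20 (adjusted p = 0.0244, and 0.408 with an estimated correlation), with the complement inhibitor gene Serping1 at 0.50 ± 0.22. Of 22 basement membrane and matrix genes 19 were higher, by a median of 0.15 (adjusted p = 0.0223, and 0.849 with an estimated correlation). Choroid plexus genes were all higher, 15 of 15, with a median of 1.95 (adjusted p = 0.00284, and 0.849 with an estimated correlation), and so were 11 of 11 ependyma genes, with a median of 0.51 (adjusted p = 0.000166, and 0.408 with an estimated correlation). The choroid plexus score was high in 3 libraries, at 4.48 in blast library Hip_8, 4.12 in blast library Hip_666 and 3.72 in sham library Hip_11, and lay between -3.46 and -0.16 in the other 7. Without these 3 hippocampus libraries the lists for cilium (median 0.59, adjusted p = 0.000595), ependyma, reactive astrocyte, myelin, complement and basement membrane were still called, and those for choroid plexus and antigen presentation were not. Among the 7 libraries then left, the cilium score was -0.84 in sham library Hip_14 and -0.94 in sham library Hip_33, against -0.25 to 0.05 in the rest.

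Genes of the molecular clock and of the glucocorticoid response fell as groups in blast hippocampus. Of 16 clock genes 11 were lower, by a median of -0.10 (adjusted p = 0.00284, and 0.408 with an estimated correlation). Of 16 glucocorticoid response genes 12 were lower, by a median of -0.11 (adjusted p = 0.007, and 0.408 with an estimated correlation). Per1, a period gene of the clock that glucocorticoids induce and that stands in both lists, had a log2 fold change of -0.25 ± 0.11, and Sgk1, a kinase gene induced by glucocorticoids, -0.35 ± 0.17. Tsc22d3, another glucocorticoid target, stood at -0.34 ± 0.14, and the clock repressors Ciart and Nr1d2 at -0.42 ± 0.19 and -0.15 ± 0.08. Of 67 cytosolic ribosomal protein genes 59 were lower, by a median of -0.09 (adjusted p = 0.00413, and 0.884 with an estimated correlation). The ribosomal score of sham library 14 was 0.87, and without that library the ribosomal median in the hippocampus was 0.08 (adjusted p = 0.000128), so the direction turned. Neither the clock nor the glucocorticoid list was called without the 3 libraries high in choroid plexus genes.

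No single gene was called in the hippocampus by edgeR over 15059 genes, where 284 had an unadjusted p under 0.05 against 753 by chance (624 without sham library Hip_14, and more still without Hip_11). No member of the 11 lists called passed either, adjusted over the list alone or over all genes tested, and fry called 0 lists. Camera called 22 lists without sham library Hip_14 and 7 without sham library Hip_13. The smallest p belonged to Map3k7 (ENSRNOG00000047516, chromosome 9, 114022137 to 114079089), the kinase TAK1 of inflammatory signalling, with 0.95 ± 0.45 CPM (SD) in blast and 8.32 ± 5.19 in sham. Its log2 fold change was -3.12 ± 0.62 (adjusted p = 0.998). DESeq2 called 1 gene and voom 0, and the table of the authors called 1, Map3k7, at -0.45 (adjusted p = 0.0373). Pld1, a phospholipase D gene, had the smallest p among genes higher in blast, at 0.53 ± 0.11, with all 5 blast libraries above all sham libraries. The same separation downwards held for Utp18 (-0.32 ± 0.08), Cntn4 (-0.34 ± 0.09) and Nbl1 (-0.37 ± 0.12), none of which passed (adjusted p = 0.998 each).

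In the amygdala, nuclear genes of the mitochondrial respiratory chain rose in blast and genes of the postsynaptic density, of myelin and of the clock fell, as groups by camera (n = 5 blast and 5 sham libraries). Camera called as many lists or more in 73 of 100 splits into 5 and 5, the real one included, so chance stays open. Of 37 respiratory chain genes 32 were higher, by a median of 0.09 (adjusted p = 2.39e-05, and 0.857 with an estimated correlation). Cox5b and Cox5a, subunits of cytochrome oxidase, had log2 fold changes of 0.32 ± 0.11 (SE) and 0.26 ± 0.09, and Ndufs7 of complex I 0.25 ± 0.09. All 16 unfolded protein response genes were higher, by a median of 0.07 (adjusted p = 0.0408, and 0.857 with an estimated correlation), with the stress transcription factor Atf4 at 0.25 ± 0.08. Of 18 postsynaptic density genes 16 were lower, by a median of -0.11 (adjusted p = 0.00599, and 0.857 with an estimated correlation). The scaffold genes Shank2, Shank1, Dlg2 and Dlg4 stood at -0.30 ± 0.07, -0.29 ± 0.13, -0.24 ± 0.09 and -0.14 ± 0.06.

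Of 18 myelin genes 16 were lower in blast amygdala, by a median of -0.11 (adjusted p = 0.00599, and 0.857 with an estimated correlation), with Mobp at -0.28 ± 0.07, Mal at -0.22 ± 0.08 and Cnp at -0.16 ± 0.06. Of 16 clock genes 12 were lower, by a median of -0.14 (adjusted p = 0.00599, and 0.857 with an estimated correlation), with Per1 at -0.30 ± 0.08, Per2 at -0.24 ± 0.10 and Nr1d2 at -0.19 ± 0.08. Choroid plexus genes were lower in 15 of 17 cases, by a median of -0.84 (adjusted p = 0.0408, and 0.965 with an estimated correlation). Adjusted over the list alone, 1 member passed in each of the postsynaptic density, myelin and clock lists, and 0 in the other 3 lists called. Over all genes tested none passed, and fry called 0 lists. With the trend of each amygdala library with gene length removed, the median of the respiratory chain list was 0.05 (adjusted p = 0.0204) and that of the postsynaptic density list -0.08 (adjusted p = 0.0325). Without sham library Amy_14 the postsynaptic density list of the amygdala stood at -0.06 and was not called (adjusted p = 0.0682).

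Single genes of the amygdala were not called by edgeR over 15280 genes, where 1325 had an unadjusted p under 0.05 against 764 by chance and the smallest adjusted p was 0.132. DESeq2 called 9 genes, voom 0 and voom with 1 surrogate variable 1. The smallest p among named genes higher in blast belonged to Atox1 (ENSRNOG00000013118, chromosome 10, 40790845 to 40805941), a copper chaperone gene, at 0.58 ± 0.10 and 23.2 ± 2.99 CPM (SD) in blast. Cstb, which codes for the protease inhibitor cystatin B, stood at 0.49 ± 0.09, and Shisa3 at 1.38 ± 0.25 (adjusted p = 0.288 for all 3). In each of these 3 genes the 5 blast libraries lay above all sham libraries. Pura (-0.54 ± 0.11), the transcription factor gene Foxp2 (-0.66 ± 0.14) and Pik3r1 (-0.32 ± 0.07), a regulatory subunit gene of phosphoinositide kinase, lay below all sham libraries in all 5 blast libraries (adjusted p = 0.459 each). The table of the authors gave an adjusted p to 2096 amygdala genes and called 17 of them, 2 higher and 15 lower. Among these, chosen after their values were seen, it gave Mast2 -0.20 (adjusted p = 0.0189), Agpat3 -0.22 (adjusted p = 0.0208), Mobp -0.24 (adjusted p = 0.039) and the proton pump gene Atp6v0c 0.22 (adjusted p = 0.0372).

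In the anterior cortex, respiratory chain and neuropeptide genes rose in blast and genes of the postsynaptic density and of oligodendrocyte precursors fell, as groups by camera (n = 5 blast and 5 sham libraries). Camera called as many lists or more in 82 of 100 splits into 5 and 5, the real one included, so chance stays open. Of 37 respiratory chain genes 34 were higher, by a median of 0.18 (adjusted p = 0.0117, and 0.992 with an estimated correlation), with Cox5a at 0.53 ± 0.25 (SE). Of 14 neuropeptide genes 12 were higher, by a median of 0.26 (adjusted p = 0.0212, and 0.992 with an estimated correlation), with Vip at 0.76 ± 0.31, Sst at 1.01 ± 0.50 and Crh, the corticotropin releasing hormone gene, at 0.80 ± 0.41. Of 18 postsynaptic density genes 17 were lower, by a median of -0.17 (adjusted p = 0.0168, and 0.992 with an estimated correlation), with Shank1 at -0.68 ± 0.23 and Shank2 at -0.49 ± 0.23. All 10 oligodendrocyte precursor genes were lower, by a median of -0.27 (adjusted p = 0.0324, and 0.992 with an estimated correlation), with the growth factor receptor gene Pdgfra at -0.32 ± 0.15 and the proteoglycan gene Cspg4 at -0.46 ± 0.23. No member of these 4 lists passed, adjusted over the list alone or over all genes tested.

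Blast library 8 and sham libraries 11, 13 and 15 stood apart in the anterior cortex. Counts were found for 16577, 17621, 17845 and 17510 genes in these libraries, against 18744 to 20748 in the other 6. Their respiratory chain scores were -0.60, -0.18, -0.33 and -0.58, against 0.24 to 0.36 in the others, and their postsynaptic density scores 0.24, 0.26, 0.19 and 0.50, against -0.25 to -0.15. Without these 4 anterior cortex libraries the median of the respiratory chain list was 0.00386 (adjusted p = 0.72) and that of the postsynaptic density list 0.07 (adjusted p = 0.397). None of the 4 lists was then called, and 6 other lists were. Leaving out blast library AC_22, blast library AC_666 or sham library AC_13 alone also brought the number of lists called to 0.

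No gene of the anterior cortex was called by edgeR over 14918 genes, where 644 had an unadjusted p under 0.05 against 746 by chance. That number was 1891 without AC_8, 1867 without AC_14 and 1111 without AC_33, and lay between 320 and 379 without AC_22, AC_11, AC_13, AC_666 or AC_88. DESeq2 and voom called 0, and 1 model of all 40 libraries called 34. That model gives a gene 1 dispersion for all regions. The common coefficient of variation between replicates was 27.8% in the anterior cortex, 23.9% in the hippocampus, 14.6% in the amygdala and 13.6% in the cerebellum. The spread this model takes for anterior cortex genes may thus be too small, and the 34 calls too many. Hif3a (ENSRNOG00000017198, chromosome 1, 78976318 to 78997869), which codes for an oxygen-regulated transcription factor, had the smallest p, at -1.72 ± 0.38, with 1.77 ± 0.59 CPM (SD) in blast and all 5 blast libraries below all sham libraries. Grm2 (ENSRNOG00000013171, chromosome 8, 115344999 to 115358046), a presynaptic glutamate receptor gene, stood at 0.73 ± 0.19 and Gucy1b1, a subunit gene of the nitric oxide receptor, at 0.45 ± 0.13. Kcnip2, a potassium channel partner, stood at -1.59 ± 0.44 and Fndc5, the precursor gene of irisin, at -0.46 ± 0.13. None of these passed (adjusted p = 0.799 each). The largest change among the named genes, 4.41 ± 1.08, belonged to 1 of 2 identifiers of Nfs1 (ENSRNOG00000045686), while the second (ENSRNOG00000019736) stood at 0.53 ± 0.69.

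In the cerebellum, genes of fibroblasts and meninges, of antigen presentation and of complement rose in blast as groups by camera (n = 5 blast and 5 sham libraries). Camera called as many lists or more in 11 of 100 splits into 5 and 5, the real one included, so chance stays open. All 16 fibroblast and meninges genes were higher, by a median of 0.90 (adjusted p = 1.6e-12, and 0.396 with an estimated correlation), with mean log2 CPM of 3.37 ± 0.36 (SD) in blast and 2.50 ± 0.74 in sham. The proteoglycan genes Lum and Dcn stood at 0.91 ± 0.22 (SE) and 0.84 ± 0.25, and the transporter gene Slc6a13 at 0.89 ± 0.23. Of 18 antigen presentation genes 14 were higher, by a median of 0.20 (adjusted p = 0.000137, and 0.0553 with an estimated correlation), led by the class II genes RT1-Da at 0.99 ± 0.21, Cd74 at 0.62 ± 0.15 and RT1-Db1 at 1.21 ± 0.31. The class I gene RT1-CE5 stood at 0.78 ± 0.20. Of 15 complement genes 14 were higher, by a median of 0.15 (adjusted p = 9.68e-05, and 0.0553 with an estimated correlation), with Serping1 at 0.55 ± 0.14 and complement factor D, Cfd, at 1.12 ± 0.36. By fry the complement and antigen presentation lists were the 2 called in the cerebellum (adjusted p = 0.0244 and 0.0252).

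Innate signalling genes rose as a group as well, with 10 of 14 higher and a median of 0.12 (adjusted p = 0.00564, and 0.198 with an estimated correlation). Ptgs2, the inducible cyclooxygenase gene, stood at 0.56 ± 0.16 and Tgfb1 at 0.42 ± 0.14. Of 20 microglia genes 13 were higher, by a median of 0.12 (adjusted p = 0.0369, and 0.501 with an estimated correlation), with the phagocytic receptor gene Trem2 at 0.35 ± 0.17. Of 21 basement membrane and matrix genes 16 were higher, by a median of 0.16 (adjusted p = 0.0237, and 0.57 with an estimated correlation), with the matrix metalloproteinase gene Mmp14 at 0.94 ± 0.19. Cilium genes were higher in 12 of 13 cases, by a median of 0.33 (adjusted p = 0.000137, and 0.481 with an estimated correlation), and ependyma genes in 10 of 10, by 0.51 (adjusted p = 7.28e-05, and 0.315 with an estimated correlation). Choroid plexus genes were higher in 12 of 12 cases, by a median of 1.5 (adjusted p = 0.00478, and 0.6 with an estimated correlation). Adjusted over the list alone, 5 members passed in the fibroblast list, 4 in antigen presentation, 3 in cilium, 1 in complement and 1 in basement membrane, and over all genes tested none did.

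Genes of the glucocorticoid response, of myelin and of the postsynaptic density fell as groups in blast cerebellum. Of 16 glucocorticoid response genes 10 were lower, by a median of -0.12 (adjusted p = 0.0366, and 0.501 with an estimated correlation), with Plin4 at -0.62 ± 0.22, Per1 at -0.34 ± 0.13 and Klf9 at -0.15 ± 0.07. Of 18 myelin genes 14 were lower, by a median of -0.06 (adjusted p = 0.0369, and 0.6 with an estimated correlation), and of 18 postsynaptic density genes 16, also by -0.06 (adjusted p = 0.0369, and 0.6 with an estimated correlation). The choroid plexus score was high in blast libraries 8 (3.04) and 22 (3.36) and in sham library 33 (2.22), and lay between -1.56 and -0.44 in the other 7. The fibroblast score was lowest in sham libraries 11 (-1.25) and 15 (-1.19). Without the 3 cerebellum libraries high in choroid plexus genes, the fibroblast list had a median of 0.79 (adjusted p = 4.41e-10), antigen presentation 0.13 (adjusted p = 0.00584) and complement 0.16 (adjusted p = 0.0082). The microglia, ependyma, innate signalling and cilium lists were then called too, and the choroid plexus, basement membrane, glucocorticoid, myelin and postsynaptic density lists were not.

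**Figure D1:**
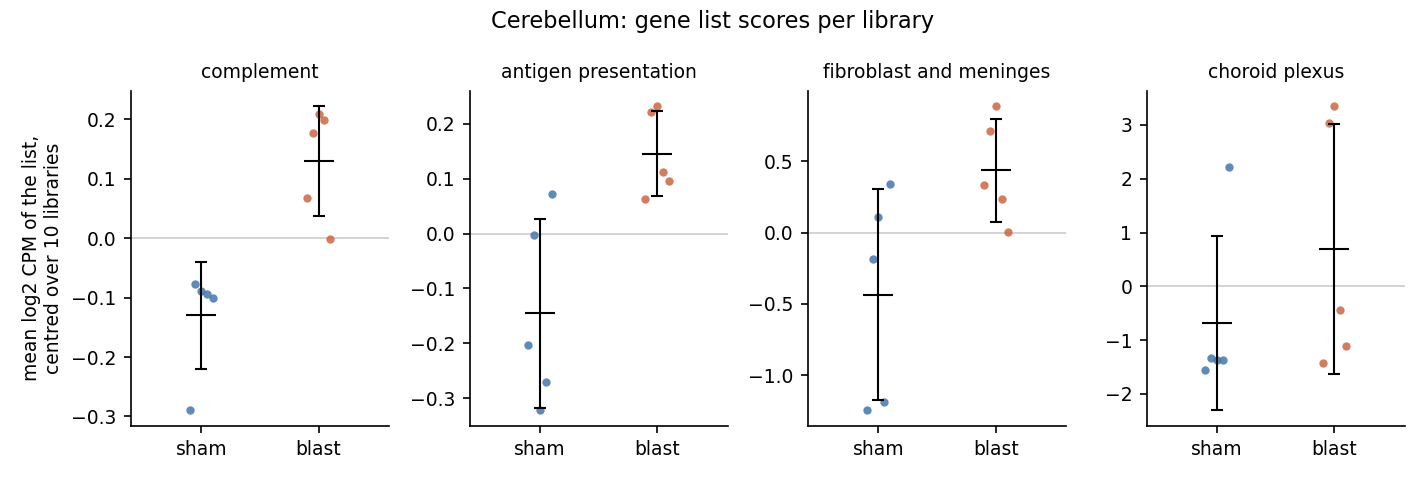
List scores of the cerebellum libraries (mean log2 CPM of a list, centred over the 10 libraries) for complement, antigen presentation, fibroblast and meninges, and choroid plexus genes. Points are libraries (blue sham, orange blast, 5 each), bars the mean ± SD; all 5 blast libraries have a higher complement score than every sham library, and 3 libraries, 2 blast and 1 sham, lie above 2 in the choroid plexus score.

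Single genes of the cerebellum were not called by edgeR over 14769 genes, where 683 had an unadjusted p under 0.05 against 738 by chance. DESeq2 called 5 and voom 0, and the table of the authors called 2, Aurkb at 0.31 (adjusted p = 0.00442) and Mmp14 at 0.31 (adjusted p = 0.00819). Aurkb (ENSRNOG00000005659, chromosome 10, 55626741 to 55634991), a mitotic kinase gene, stood here at 1.18 ± 0.21 (adjusted p = 0.564), with 6.33 ± 1.58 CPM (SD) in blast. Mmp14 (ENSRNOG00000010947, chromosome 15, 33074441 to 33083655) had 17.2 ± 4.46 CPM in blast. In both genes, and in the kinase gene Ikbke at 0.80 ± 0.17 and the chemerin gene Rarres2 at 0.78 ± 0.17 (adjusted p = 0.764 each), all 5 blast libraries lay above all sham libraries. Among genes lower in blast were Hnrnpab, which codes for an RNA-binding protein, at -3.00 ± 0.53 (adjusted p = 0.564), Hif3a at -1.33 ± 0.29 (adjusted p = 0.764) and Tril, a partner of Toll-like receptors, at -0.17 ± 0.04 (adjusted p = 0.764).

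**Figure D2:**
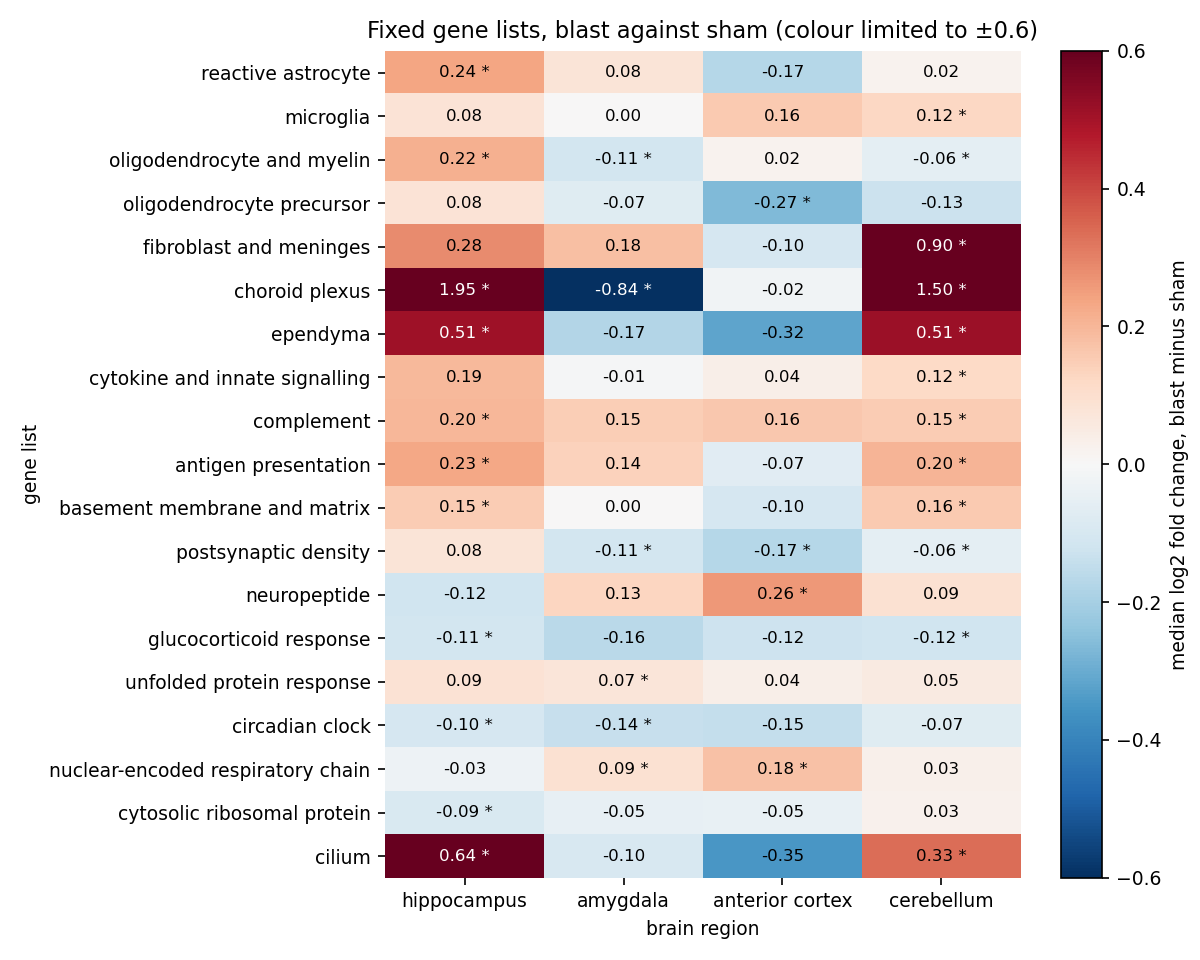
Median log2 fold change of blast against sham (colour, limited to 0.6 either way, and number in each cell) for each gene list that camera called in at least 1 region, by brain region; a star marks an adjusted p under 0.05 with the preset correlation. Choroid plexus genes range from -0.84 in the amygdala to 1.95 in the hippocampus, and the clock list is below 0 in all 4 regions.

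Whether the blast effect differed between regions was tested directly, since a call in 1 region and not in another is no test of a difference. The interaction test of edgeR called 0 of 16378 genes, with 779 at an unadjusted p under 0.05 against 819 by chance. The same test by voom with the title number as a random block also called 0. The smallest p belonged to Igbp1b, at -0.50 in the hippocampus and 0.42 in the amygdala (adjusted p = 0.507). Kcnip2 followed, with log2 fold changes of 0.52 in the hippocampus, -0.33 in the amygdala and -1.59 in the anterior cortex (adjusted p = 0.517). The cytokine gene Mif stood at -3.99, 4.21, -3.65 and -0.41 in the hippocampus, amygdala, anterior cortex and cerebellum (adjusted p = 0.67). The myelin list, higher in blast hippocampus and lower in blast amygdala, differed between the 2 by 0.32 on the log2 scale (exact two-sided permutation p = 0.222, adjusted p = 0.31). The choroid plexus list differed between these regions by 2.37 (exact two-sided permutation p = 0.31, adjusted p = 0.31).

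Across genes, the blast effects of the amygdala and the anterior cortex were the most alike of the 6 pairs of regions, with a Pearson correlation of 0.331 and a Spearman correlation of 0.486 over 14725 genes. Over genes with a mean log2 CPM over 5 the Pearson correlation of this pair was 0.767, and those of the hippocampus with the amygdala and the anterior cortex and of the cerebellum with the same 2 regions were -0.259, -0.315, 0.262 and 0.307. Over all genes the hippocampus and the cerebellum had correlations of 0.264 (Pearson) and 0.0866 (Spearman), and the Pearson value was as low as 0.14 with 1 number left out. The hippocampus had correlations of -0.0922 and -0.15 with the amygdala and of -0.117 and -0.237 with the anterior cortex. The cerebellum had 0.123 and 0.24 with the amygdala and 0.105 and 0.215 with the anterior cortex. Genes are not independent replicates, so these values carry no p from the number of genes. Leaving out sham number 14 turned the Pearson correlation of the hippocampus with the anterior cortex to 0.109.

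Averaged over the 4 regions, blast libraries had less Sla2 transcript, and clock genes fell as a group. Sla2 (ENSRNOG00000020337, chromosome 3, 152944452 to 153001309), which codes for an adaptor that dampens lymphocyte receptor signalling, had a mean log2 fold change of -1.17 ± 0.21 (SE, adjusted p = 0.0469) by limma. It stood at -1.26 in the hippocampus, -0.88 in the amygdala and -1.31 in the anterior cortex, where blast held 1.02 ± 0.37 CPM (SD), and was not tested in the cerebellum alone. Of 16 clock genes 13 were lower in the mean effect, by a median of -0.14 (adjusted p = 2.89e-07, and 0.00222 with an estimated correlation), and 6 of them passed, adjusted over the list alone, while none did over all genes tested. The block correlation of this fit was 0.02, so libraries of 1 number counted as nearly independent, for Sla2 as well. For Per1, however, the blast libraries of numbers 4 and 8 were lower than the other blast libraries in each region. The SE and p-values of Per1 and of the clock list in this fit may therefore be too small. On scores per title number the clock difference had an exact two-sided permutation p of 0.0476, and 0.397 adjusted over the 50 lists. Per1 had a mean effect of -0.29 ± 0.06 (adjusted p = 0.0808), Nr1d2, which codes for a nuclear receptor of the clock, -0.20 ± 0.04 (adjusted p = 0.0783), Per2 -0.24 ± 0.08 and the transcription factor gene Tef -0.12 ± 0.03. Per2 and Tef, like Arntl below, were chosen after their values were seen. Per1, Per2, Nr1d2 and Tef were lower in blast in all 4 regions, whereas Arntl, the gene of the activating partner of Clock, was higher in all 4 with a mean effect of 0.15 ± 0.06 (adjusted p = 0.503).

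Glucocorticoid response genes fell as a group in the mean effect, with 12 of 16 lower and a median of -0.10 (adjusted p = 0.00162, and 0.397 with an estimated correlation). Sgk1 had a mean effect of -0.39 ± 0.09 (adjusted p = 0.117) and was lower in all 4 regions. The 4 genes of this list that were higher were Cdkn1a (0.35), Mt1 (0.20), Mt2A (0.18) and Arrdc2 (0.08), and Fkbp5 stood at -0.08 ± 0.05. These 5 were chosen after their values were seen. Among the other groups called were fibroblast and meninges genes, with 15 of 16 higher and a median of 0.33 (adjusted p = 0.000174, and 0.661 with an estimated correlation), complement, with 16 of 17 higher and 0.16 (adjusted p = 0.00786, and 0.637 with an estimated correlation), and antigen presentation, with 16 of 21 higher and 0.25 (adjusted p = 0.00789, and 0.661 with an estimated correlation). Cilium genes (median 0.22, adjusted p = 0.0145, and 0.718 with an estimated correlation), unfolded protein response genes (0.07, adjusted p = 0.0094, and 0.661) and respiratory chain genes (0.06, adjusted p = 0.00786, and 0.967) were also higher as groups. Genes of the postsynaptic density (-0.07, adjusted p = 0.00786, and 0.93 with an estimated correlation), of oligodendrocyte precursors (-0.07, adjusted p = 0.0419, and 0.661), of the cytosolic ribosome (-0.04, adjusted p = 0.0094, and 0.967) and markers of the striatum (-0.10, adjusted p = 0.037, and 0.667) were lower. In all 50 lists were tested and 12 called in this way, 1 of them, the clock, also with an estimated correlation. Per title number the clock score was -0.06 ± 0.09 (SD, n = 5) in blast and 0.06 ± 0.06 in sham, and 4 of the 5 blast numbers lay below all sham numbers. That difference of -0.12 had an exact two-sided permutation p of 0.0476, and 0.397 adjusted over the 50 lists.

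Hif3a was the next gene after Sla2 by p, at -1.18 ± 0.23 (adjusted p = 0.0573), lower in all 4 regions. Fndc5 stood at -0.22 ± 0.04 (adjusted p = 0.0778), the histone chaperone gene Asf1b at -1.49 ± 0.31 (adjusted p = 0.0778) and Grm2 at 0.66 ± 0.14 (adjusted p = 0.0796). In all, 1 gene of 16378 was called, 8 had an adjusted p under 0.1, and 1369 an unadjusted p under 0.05 against 819 by chance. The call of Sla2 ended when any 1 of the 5 blast numbers, or sham number 13, was left out, with adjusted p from 0.0575 to 0.189. It also ended in a limma fit of means per title number, where no gene was called. Leaving out sham number 14 brought the number of genes called to 25 and that at an unadjusted p under 0.05 to 2798.

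**Figure D3:**
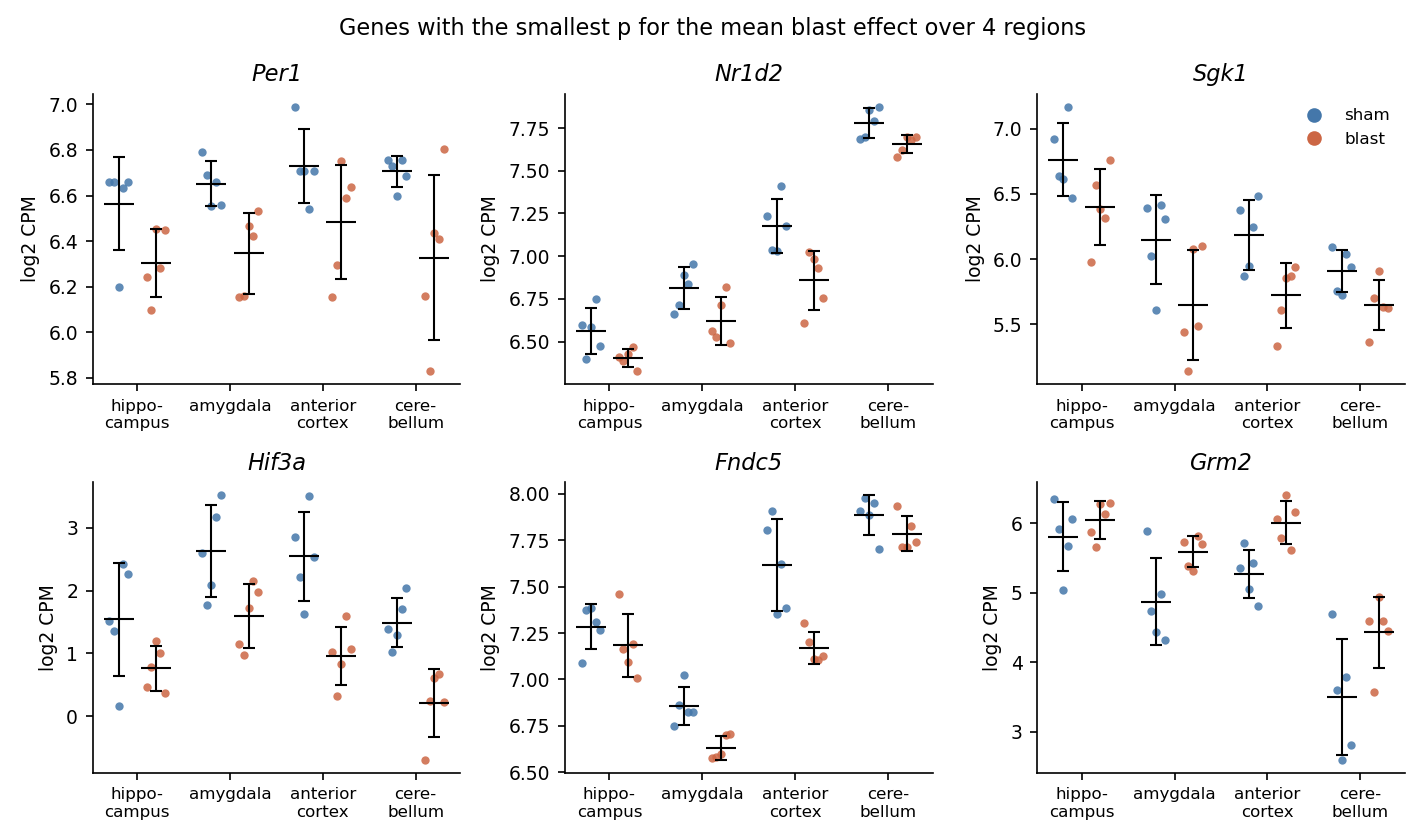
Log2 CPM of Per1, Nr1d2, Sgk1, Hif3a, Fndc5 and Grm2 in each library by brain region (blue sham, orange blast, 5 libraries each, bars mean ± SD), all 6 among the genes with the smallest p for the mean effect; Sla2 and Asf1b, also among them, are not shown. Hif3a is lower in blast on average in all 4 regions (mean effect -1.18) and Grm2 higher (0.66), while most groups overlap.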

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

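The removal of libraries that stood apart, the removal of length trends, the 2 scores used together as covariates and the counts over other splits were chosen only after results had been seen. Of 98 groups of 5 libraries tested for a library far from the other 4, 7 had one, where chance gives about 5. The measure is the gap to the nearest library divided by the range of the group. In the anterior cortex, blast library AC_22 had 37128383 counts (0.908), and blast library AC_8 lay far from the other blast libraries in its postsynaptic density score (0.245, measure 0.813), its neuropeptide score (-0.738, measure 0.722) and its respiratory chain score (-0.601, measure 0.874). In the cerebellum, sham library Cer33 had a choroid plexus score of 2.21 (0.942) and sham library Cer11 a complement score of -0.29 (0.888). In the hippocampus, sham library Hip_14 had a ribosomal score of 0.87 (0.722).

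Respiratory chain genes were higher and postsynaptic density genes lower in blast in both the amygdala and the anterior cortex. In the amygdala the tables argue against a trend with gene length as the whole cause, since 0.574 of the median of the respiratory chain list and 0.742 of that of the postsynaptic density list were kept with the trend removed, and camera with the preset correlation still called both. In the anterior cortex 0.51 and 0.871 were kept, but neither list was still called (medians of 0.09 and -0.15, adjusted p = 0.107 and 0.0775), which leaves the length trend open there. The 4 anterior cortex libraries AC_8, AC_11, AC_13 and AC_15 may account for that region's calls, as 0.0217 and -0.419 of the medians were kept without them. In the amygdala, with each library left out in turn, camera with the preset correlation called the respiratory chain list each time (medians of 0.06 to 0.14). It called the postsynaptic density list except without sham Amy_14 (-0.06, adjusted p = 0.0682). Neither list was called in the amygdala with an estimated correlation, and 73 of 100 splits called as many lists there. An effect of blast and chance both stay open there, and why the 4 anterior cortex libraries differ was not tested.

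Complement and antigen presentation genes were higher in blast cerebellum. With the fibroblast and meninges score and the choroid plexus score as covariates, the complement list kept 1.02 of its median (0.15, adjusted p = 0.0199). The antigen presentation list kept 0.696 (0.14, adjusted p = 0.0154), both by camera with the preset correlation. These scores thus did not take up the whole difference. Each is a mean of listed genes and may miss part of the tissue carried along in the dissection. Such tissue is therefore not excluded as the source. Blood in the tissue cannot be told apart for either list. Hemoglobin genes took 0.0219 ± 0.00788% (SD, n = 5) of counts in blast and 0.0207 ± 0.00398% in sham, a log2 difference of 0.0352 (exact two-sided permutation p = 0.889), too small and too variable to decide. A lasting immune response to blast remains a hypothesis, as both lists missed the threshold with an estimated correlation (adjusted p = 0.0553).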

How the results depend on the processing

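The surrogate variable, the 2 scores as covariates, the length trend and the removal of libraries that stood apart were chosen after seeing the data. The edgeR tests of single genes used counts. The prior count of 2 in the log2 CPM of the list tests and scores was not varied. Genes called by region were 0 by edgeR in all 4 regions. In the hippocampus DESeq2 gave 1, and leaving out 1 library gave 0 to 1 (1 without sham Hip_33). In the amygdala the count was 2 with no low-count filter, 9 by DESeq2, 1 with a surrogate variable and 0 to 2 with 1 library left out (1 without blast Amy_88, 1 without the unnumbered library and 2 without sham Amy_33). In the anterior cortex it was 34 in 1 model of all 40 libraries and 2 without AC_8, AC_11, AC_13 and AC_15. In the cerebellum it was 5 by DESeq2 and 0 to 1 with 1 library left out (1 without sham Cer14 or sham Cer33). With DESeq2 size factors, voom, quality weights or a CPM filter it stayed at 0 in all 4 regions, where edgeR gave 284, 1325, 644 and 683 genes at an unadjusted p under 0.05. Quality weights gave 2994 such genes in the anterior cortex, and the model of all 40 libraries 602, 367, 2923 and 342. The latter model shares 1 dispersion per gene over the regions, so its counts in the anterior cortex may be too high.

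Lists called by camera fell to 0 in all 4 regions with an estimated correlation. By fry they fell to 0 in the hippocampus, amygdala and anterior cortex and to 2 in the cerebellum. Leaving out 1 library gave 7 to 22 in the hippocampus (7 without sham Hip_13, 22 without sham Hip_14), 4 to 11 in the amygdala (4 without blast Amy_88 or the unnumbered library, 10 without blast Amy_22, 11 without sham Amy_15), 0 to 7 in the anterior cortex (7 without blast AC_4, 0 without blast AC_22, blast AC_666 or sham AC_13) and 9 to 14 in the cerebellum. The count was 14 in the amygdala with the choroid plexus and fibroblast scores as covariates, 2 in the anterior cortex with the length trend removed and 7 in the cerebellum without Cer8, Cer22 and Cer33. The cause was not tested.

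The test of differences between regions gave 0 genes in each alternative, with the title number as a random block (903 at an unadjusted p under 0.05), as a fixed block (697), with DESeq2 size factors (762), with a CPM filter (736) or without the cerebellum. The mean effect gave 2 genes without a replicate block, 0 with means per title number, and 0 to 25 with 1 number left out. Of these removals, blast 4, 8 and 88 and sham 13 gave 0, sham 11, 15 and 33 and the unnumbered library 2, the blast number of AC_666 4, and sham 14 25. Deviations of libraries from their group means, correlated between regions, had a median of 0.0708 over 57 pairs of 1 number (from -0.151 to 0.439, 19 over 0.1) and of -0.0208 over 243 pairs of different numbers (24 over 0.1). A library correlated best with its own number in 60 of 114 cases, against 22.8 by chance, a hint of pairing from the data that not every pair shows. The Pearson correlations over genes with a mean log2 CPM over 5 were -0.259 for hippocampus and amygdala, -0.315 for hippocampus and anterior cortex, 0.767 for amygdala and anterior cortex, 0.262 for amygdala and cerebellum and 0.307 for anterior cortex and cerebellum. With 1 number left out the correlations over all genes tested ran from -0.17 to -0.00488, -0.176 to 0.109, 0.244 to 0.339, 0.0554 to 0.192 and 0.00707 to 0.13 in the same order, and from 0.14 to 0.328 for hippocampus and cerebellum.

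Of 4351 alternative values of 227 results for named genes, 4304 kept direction and side of the threshold, 30 passed it (23 genes) and 7 lost it, all of them for Sla2 (adjusted p from 0.0575 to 0.256). Only Sla2 passed in the main fits, so for the other results keeping the side means staying uncalled. The genes were chosen by p in these same data, and the F values of the interaction have no direction. The counts are thus no support for the named genes. The direction turned in 10 values of 6 results. With a surrogate variable these were Kcne2 (-0.19), Sostdc1 (-0.32) and Cldn2 (-0.33) in the hippocampus and Slc4a5 (-0.15) in the cerebellum, and with the choroid plexus score as covariate Kcne2 (-0.16), Cldn2 (-0.0173) and Slc4a5 (-0.0713) in the same regions. Without the libraries high in choroid plexus genes Cldn2 stood at -0.13 in the hippocampus and Kcne2 at -0.0268 in the cerebellum, and without the 4 libraries that stand apart Ndufa4 stood at -0.0501 in the anterior cortex. The cause was not tested.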

Other observations

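The test of clock phase and the counts over other splits of the samples were chosen only after the results they measure had been seen, and so was the test of lists on the mean effect. Besides Per1, Per2, Nr1d2 and Tef, the clock genes Ciart (-0.24), Per3 (-0.15), Bhlhe41 (-0.12), Dbp (-0.22) and Hlf (-0.22) had a mean effect below 0 and were lower in blast in all 4 regions, and Nr1d1 stood at 0.02. These genes were chosen after their values were seen. The tissue scores per title number were also compared. Complement (0.195, exact two-sided permutation p = 0.0238), ependyma (0.208, exact p = 0.0317), antigen presentation (0.217, exact p = 0.0317) and the unfolded protein response (0.104, exact p = 0.0476) were higher in blast numbers. Cortical layer markers were lower (-0.0996, exact p = 0.0476), and none of these lists passed over the 50 lists (adjusted p = 0.397 each). The myelin list differed between hippocampus and cerebellum by 0.26 (exact p = 0.31) and the choroid plexus list between cerebellum and amygdala by 2.04 (exact p = 0.19), with an adjusted p of 0.31 for each.

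Clock and glucocorticoid response genes were lower in blast in the mean over the 4 regions, and a lasting change of the clock or of the stress axis after blast may be a candidate explanation that stays open. The fixed stress axis list was not called in the mean effect (median -0.06, adjusted p = 0.2996 by camera with the preset correlation). Its score per title number differed by -0.0276 (exact two-sided permutation p = 0.714). The tables argue against a trend with gene length, since 1.05 of the clock score difference was kept with the trend removed, and against 1 title number making the clock difference, since 0.841 was kept in the lowest case. The glucocorticoid difference of -0.09 kept 0.6 without number 11 and did not pass (exact two-sided permutation p = 0.206, adjusted p = 0.687), so chance stays open for that list. Of the 126 splits of the title numbers 6, the real one included, gave a clock difference as far from 0. It was -0.12 in the real split and 0.15 either way in the highest other. The clock list was taken up after the data had been seen, and it did not pass over the 50 lists (adjusted p = 0.397). Chance is thus not excluded for it. A different clock phase at collection cannot be told apart. The genes taken here to peak opposite to Per1 had a median mean effect of 0.0111, between the bounds set for either answer. They were mixed, with Arntl at 0.15, Nfil3 at 0.08, Npas2 at 0.01, Cry1 at -0.01 and Clock at -0.04. The median thus depends on the choice of genes, and the hour of collection is not given in the sources used here.

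Other splits of the same libraries into 5 and 5, 100 with the real one, were counted for each result. For the genes called in each region the real count was 0, which all 100 splits reach by construction, so this count says nothing about chance. The highest of the other splits called 2 genes in the hippocampus, 149 in the amygdala, 2820 in the anterior cortex and 9 in the cerebellum. For lists called chance cannot be excluded, with 11 in the real split and 46 splits as large in the hippocampus (highest other 21), 6 and 73 in the amygdala (30), 4 and 82 in the anterior cortex (24) and 12 and 11 in the cerebellum (17). It cannot be excluded for the mean effect either (1 gene, 82 splits, highest other 743). For the difference between regions the real count of 0 decides nothing (100 splits, highest other 1950). Counts at an unadjusted p under 0.05 above the chance expectation leave chance open too, since 14 of 100 splits reached the 1325 of the amygdala (highest other 2713) and 17 the 1369 of the mean effect (highest other 4320). The splits with 2820 and 743 genes are the same one. It sets sham number 14 with all blast numbers but 8, and so puts the anterior cortex libraries AC_8, AC_11, AC_13 and AC_15 on 1 side with AC_33, which points to a structure of those libraries.

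For the correlation of blast effects between the amygdala and the anterior cortex 2 of 100 splits were as far from 0 (0.331 in the real split, 0.347 in the highest other). This value was not computed without the anterior cortex libraries that stood apart. The pair stands out as the largest of the 6 correlations. A largest correlation of that size came in 13 of 100 splits (highest other 0.5), so chance is not excluded. It cannot be excluded for the hippocampus with the amygdala (26 splits, -0.0922, farthest other -0.209), with the anterior cortex (51 splits, -0.117, highest other 0.428) and with the cerebellum (9 splits, 0.264, highest other 0.5), or for the cerebellum with the amygdala (36 splits, 0.123, highest other 0.279) and with the anterior cortex (26 splits, 0.105, highest other 0.207).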
